A study of Mus musculus with 44 samples.

How the data were processed

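Total RNA of 43 samples labelled lymphoma and 1 labelled spleen, all from Eµ-myc mice, had been labelled with biotin and hybridised to Affymetrix mouse arrays, 1 array per sample. Lymphoma tissue had been frozen directly, or cells of lymphomas and spleens had been suspended and frozen as pellets, and the labels do not tell which array followed which route. Per the labels, the deposited values are log2 expression values per probe set made by the authors with RMA in the affy package, with no versions given. The table held 22690 probe sets, 64 of them controls, with 0 missing values and a range of 2.36 to 14.93. Every column was mapped to a sample. Precision was set by the number of arrays, since arrays have no read depth.

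The sorted column medians showed a largest gap of 0.402, against 0.0854 for the second largest. The gap separated 36 lymphomas with title numbers 34 to 117 (column means 6.61 to 6.64) from the spleen and 7 lymphomas with title numbers 121 to 168 (means 7.24 to 7.25), as when RMA is run on each set separately. The labels do not state such runs. All comparisons therefore carried the set as a covariate or used values minus the set mean of the lymphomas. The fit without the set, which had been planned before the data were examined, was kept as an alternative and its counts are given beside each result. The gene lists, the pairs of scores, the tests, the rule for named genes and most alternatives were also chosen before the data were examined.

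Of 22626 other probe sets, 20380 had 1 gene symbol and were used, 691 with several symbols and 1555 with none were left out. Their symbols were checked against the annotation of the GRCm38.p6 assembly by Entrez identifier, which 20351 matched and 0 of which were renamed. For each of 12393 genes the probe set with the highest mean was taken, and a gene was kept if at least 1 array lay above the median of its set, which left 8721 genes. A score was the mean of a list's kept genes minus the set mean of the lymphomas. There were 28 lists of cell type markers and pathways, of which 26 had the 5 genes needed for a test.

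The spleen was compared with the lymphomas, and each gene was regressed on Myc, on Cdkn2a or on the B cell stage score (mature minus precursor B cell score), with limma 3.58.1 in R 4.3.3, using eBayes with an intensity trend, two-sided tests and Benjamini-Hochberg adjustment at 0.05. The spleen fit had 41 residual degrees of freedom from the spread of the lymphomas. Lists in the spleen were tested with camera at a preset correlation of 0.01, with the estimated correlation beside it. Coherence of a list was its mean pairwise Pearson correlation against 10000 random lists matched on expression in 20 bins, with a one-sided permutation p. Correlations of scores had 23 planned pairs with two-sided permutation tests (100000 permutations, or all 5040 orders for the 7 lymphomas of set 2), adjusted over the family. A score was treated as clustered when a 2-component mixture (mclust 6.1.1) gained a BIC difference of more than 10 with an Ashman D above 3 and at least 3 lymphomas in each component, and correlations were then computed within a component of at least 6 lymphomas.

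The named genes were the 12 highest and 12 lowest differences in the spleen among those past the threshold and outside the range of the lymphomas, the 25 genes with the highest SD, the 10 most positive and 10 most negative slopes of each regression, up to 4 members of each list with the largest statistic, and the single genes Myc, Mycn, Cdkn2a, Xist, Eif2s3y, Kdm5d and Uty. Trp53 and Ddx3y, also on that list, were not analysed here. The alternatives concerned the filter, the choice of probe set, quantile or median scaling, eBayes settings, array weights (statmod 1.5.0), the 3' minus 5' control difference, the title number, the T cell and macrophage scores, ranks, and leaving out the 2 lymphomas farthest from the median. The set covariate was added after seeing the data, which turned the planned fit without it into an alternative. Fits within each set, without lymphomas 9, 13, 32 and 40, with 6 other-cell scores as covariates, and with the spread of the 7 set 2 lymphomas alone were added then too, as were array weights and the 3' minus 5' covariate for camera, and regressions over the 36 lymphomas of the lower germinal centre component.

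The pipeline was tested on simulated data with 8721 genes. Changes of 1, 2 and 3 log2 units in 1 array were called in 27%, 76% and 87.5% of genes. Slopes of 0.5 residual SD per SD of the predictor were called in 23% (Myc), 21% (stage) and 28% (Cdkn2a) of genes, and slopes of 1 residual SD in 99.5%, 100% and 99.5%. Unchanged genes made up 8.48%, 5% and 5.41% of the calls in 1 array, and at slopes of 1 residual SD 6.57%, 6.10% and 3.40% of them. At slopes of 0.25 residual SD 1% (Myc), 0% (stage) and 0% (Cdkn2a) of genes were called, and unchanged genes made up 100% of the stage calls. The simulated noise was normal and drawn independently for each gene, whereas real genes were correlated, so these shares need not hold for the real data. A simulated list correlation of 0.5 was recovered as 0.496 and its absence as -0.0037. The highest correlation between 2 arrays was 0.991, so no array was a copy of another.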

Results

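The series comprised 44 Affymetrix arrays hybridised with total RNA from Eµ-myc mice, which carry a Myc transgene driven by the immunoglobulin heavy chain enhancer and develop B cell lymphomas. Of these, 43 arrays were labelled lymphoma and 1 was labelled spleen. The labels do not say that each lymphoma came from a different animal, nor that the spleen was free of disease, and they give no treatment, age or sex. The title of the spleen array opens with the same words as those of the lymphomas, Eµ-myc Lymphoma Test, and adds Spleen in brackets. The number of arrays, not a read depth, limited the precision. The arrays fell into 2 sets by their column medians, 36 lymphomas with medians of 6.21 to 6.45 (set 1) and 7 lymphomas together with the spleen with medians of 6.85 to 7.01 (set 2). All comparisons below were made with the set taken into account, and levels are log2 values within a set.

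Myc was expressed at 10.46 ± 0.57 (SD, n = 36) in set 1 and at 11.16 ± 0.62 (SD, n = 7) in set 2. The level in the spleen was 10.09, and the difference of -1.07 ± 0.60 (SE) from the set 2 lymphomas did not pass the limma test (adjusted p = 0.239). The array does not distinguish transgenic from endogenous Myc mRNA. Mycn stayed near 6.91 ± 0.17 (SD, n = 36) in set 1 and 7.44 ± 0.05 (SD, n = 7) in set 2. Cdkn2a, which encodes the p16Ink4a and p19Arf tumour suppressors, ranged from 3.97 to 11.46 in set 1, with a mean of 7.68 ± 2.31 (SD, n = 36). Trp53 and Ddx3y were not analysed here.

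The first comparison set the single spleen against the lymphomas. Rhag, a red cell membrane protein gene, stood at 12.32 in the spleen and at 3.98 ± 0.11 (SD, n = 7) in the lymphomas of its set, a difference of 8.34 ± 0.22 (SE; limma adjusted p = 3.22e-31). The platelet chemokine gene Ppbp was higher by 7.77 ± 0.36 (SE) and the immunoglobulin heavy chain gene Ighg3 by 7.65 ± 1.14 (SE). Genes lower in the spleen included Bcat1, a branched-chain amino acid transaminase, at -3.84 ± 0.93 (SE), and the lymphocyte genes Slamf6 (-2.91 ± 0.95), Ptprcap (-2.80 ± 0.44) and Rhoh (-2.73 ± 0.51). Without the set in the fit, 7 of the 12 lowest differences stayed past the threshold against 12 of the 12 highest, and Slamf6 did not.

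The 11 erythroid genes that passed the filter were all higher in the spleen, by 4.07 to 8.34 log2 (median 6.88). Besides Rhag these included Klf1, the erythroid transcription factor (6.88 ± 0.21, SE), and the blood group genes Ermap (6.62 ± 0.20) and Kel (6.77 ± 0.21). The set 1 median levels of erythroid and megakaryocyte genes (4.86 and 5.45) lay under that of all probe sets (6.28). The filter counted the spleen, so genes low in the lymphomas could be kept through the spleen alone. For these 2 lists the share of genes that were higher is therefore partly built in. Of 6 megakaryocyte genes 5 were higher, among them Itga2b (3.16 ± 0.21) and Gp9 (3.06 ± 0.21), and all 6 when adjusted over the list alone (adjusted p = 4.74e-17, and adjusted p = 4.11e-07 with an estimated correlation). Neutrophil granule genes were higher in 9 of 11 cases, or 11 when adjusted over the list alone, with Elane at 5.13 ± 0.43 and Mpo at 6.07 ± 1.28 (adjusted p = 2.03e-09, but adjusted p = 0.209 with an estimated correlation). The carbonic anhydrase genes Car2 and Car1 (7.62 ± 1.67 and 7.09 ± 0.32), the water channel gene Aqp1 (7.49 ± 1.32), Hemgn (7.39 ± 0.77), the heme synthesis gene Alas2 (6.97 ± 0.31) and the anion exchanger gene Slc4a1 (6.94 ± 0.34) were also among the 12 highest differences. Tent5c (7.02 ± 1.67) and the interferon-induced Rsad2 (7.0 ± 1.25) completed them.

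Of 17 stroma and endothelium genes 6 were higher in the spleen, or 11 when adjusted over the list alone. Examples were Vwf (4.77 ± 0.82, SE) and Col4a2 (6.0 ± 1.44). The list test gave adjusted p = 5.02e-06, and adjusted p = 0.520 with an estimated correlation. Of 19 macrophage genes 4 were higher, also when adjusted over the list alone, including Spic (2.04 ± 0.39) and Hmox1 (3.0 ± 0.84), both active in the macrophages that clear red cells (adjusted p = 0.000166, but adjusted p = 0.588 with an estimated correlation). Plasma cell genes were higher for 3 of 10 members, or 5 when adjusted over the list alone. They were Ighg3, Prdm1 (3.79 ± 1.01) and Xbp1 (2.78 ± 0.89), with adjusted p = 0.000877 for the list and adjusted p = 0.343 with an estimated correlation. The unfolded protein response genes Sel1l (3.60 ± 0.52) and Trib3 (2.12 ± 0.26) were among 5 of 14 that were higher, or 9 when adjusted over the list alone (adjusted p = 4.39e-07, and adjusted p = 0.200 with an estimated correlation). Of 20 interferon response genes only Rsad2 was higher, also when adjusted over the list alone (adjusted p = 0.0443, and adjusted p = 0.850 with an estimated correlation).

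Ribosome biogenesis genes were lower in the spleen for 14 of 23 members, or 21 when adjusted over the list alone. They included Npm1 (-0.87 ± 0.17, SE), the nucleolar methyltransferase gene Fbl (-1.12 ± 0.28) and Nop16 (-1.60 ± 0.40), with a list adjusted p = 4.39e-07 and adjusted p = 0.436 with an estimated correlation. Metabolic genes known as MYC targets were lower for 4 of 17 members, or 6 lower and 2 higher when adjusted over the list alone. Hspe1 (-0.95 ± 0.21) and Ldha (-0.92 ± 0.21) were among them (adjusted p = 0.0443, and adjusted p = 0.730 with an estimated correlation). Ribosomal protein genes were lower for 5 of 16 members, or 6 when adjusted over the list alone, with Rpl11 at -0.59 ± 0.10 (adjusted p = 0.00391, and adjusted p = 0.560 with an estimated correlation). Without the set in the fit, Rpl11 lay at 0.12 and the ribosomal protein list gave adjusted p = 0.933 in the upward direction.

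B cell gene lists did not pass the list test (camera adjusted p = 0.346 for pan B cell, 0.115 for mature and 0.772 for precursor B cell genes). Of 9 pan B cell genes 0 passed, also when adjusted over the list alone, with Cd79a at -2.12 ± 1.11 (SE). Of 15 mature B cell genes only Igk was lower, also when adjusted over the list alone, at -2.46 ± 0.64. That value turned to 0.82 when the probe sets of Igk were averaged, and probe sets of immunoglobulin genes can read related sequences. Of 13 precursor B cell genes only the receptor gene Kit was higher, at 2.51 ± 0.65, also when adjusted over the list alone. T cell (16 genes), NK and cytotoxic (10), MHC class II (9), adipocyte (5), NF-kB (11), germinal centre (4) and skeletal muscle (3) lists had 0 genes past the threshold, also when adjusted over each list alone. The DNA damage gene Gadd45a (3.34 ± 0.50) was the only p53 target of 16 that was higher, and the proliferation marker Mki67 (1.01 ± 0.31) the only G2/M gene of 23. In the BCL2 family (9 genes) the survival gene Bcl2l1 (2.72 ± 0.30) was higher and Bid (-1.62 ± 0.46) lower, and among 23 S phase genes Rrm2 (1.08 ± 0.32) and Tyms (1.41 ± 0.42) were higher and Ung (-1.44 ± 0.39) lower. These counts were the same when adjusted over each list alone, while Zfp36 (1.27 ± 0.43), the only immediate early gene of 14 that was higher, did not pass then. Glycolysis and hypoxia had 3 of 16 genes lower, Tpi1 at -1.39 ± 0.36 among them, also when adjusted over the list alone. Oxidative phosphorylation had 4 of 27 lower, such as Cycs at -0.91 ± 0.21, or 6 when adjusted over the list alone, and the other lower members Sdhb, Uqcrc2 and Cox5a turned to 0.10, 0.23 and 0.12 without the set. The median was negative and the list test pointed upward for the NK and cytotoxic, BCL2 family and immediate early lists, and the mean was negative for the first of them. In all, 11 of 26 lists passed camera, but only 2 did with an estimated correlation. Without the set 13 passed, among them the pan, mature and precursor B cell, MHC class II and T cell lists as lower in the spleen, and again only 2 did with an estimated correlation.

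Over all 8721 genes, limma called 663 higher and 505 lower in the spleen, of which 586 and 274 differed at least 2-fold. The balance depended on the method, with 594 higher and 776 lower with equal column medians and 1102 and 1347 with array weights. The median of all differences was -0.16, and it was -0.30 with equal column medians and 0.42 without the set. Without the set in the fit or in the filter, as the comparison had first been planned, 1207 of 9103 genes were higher and 41 lower, of which 659 and 37 were shared. The spleen lay above the range of all 43 lymphomas for 753 genes and below it for 1053, which is 20.7% of genes against 4.55% by chance. With 1 spleen the test assumed that it varied as the lymphomas did, and lymphoma 13 singled out in the same way gave 990 genes.

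**Figure D1:**
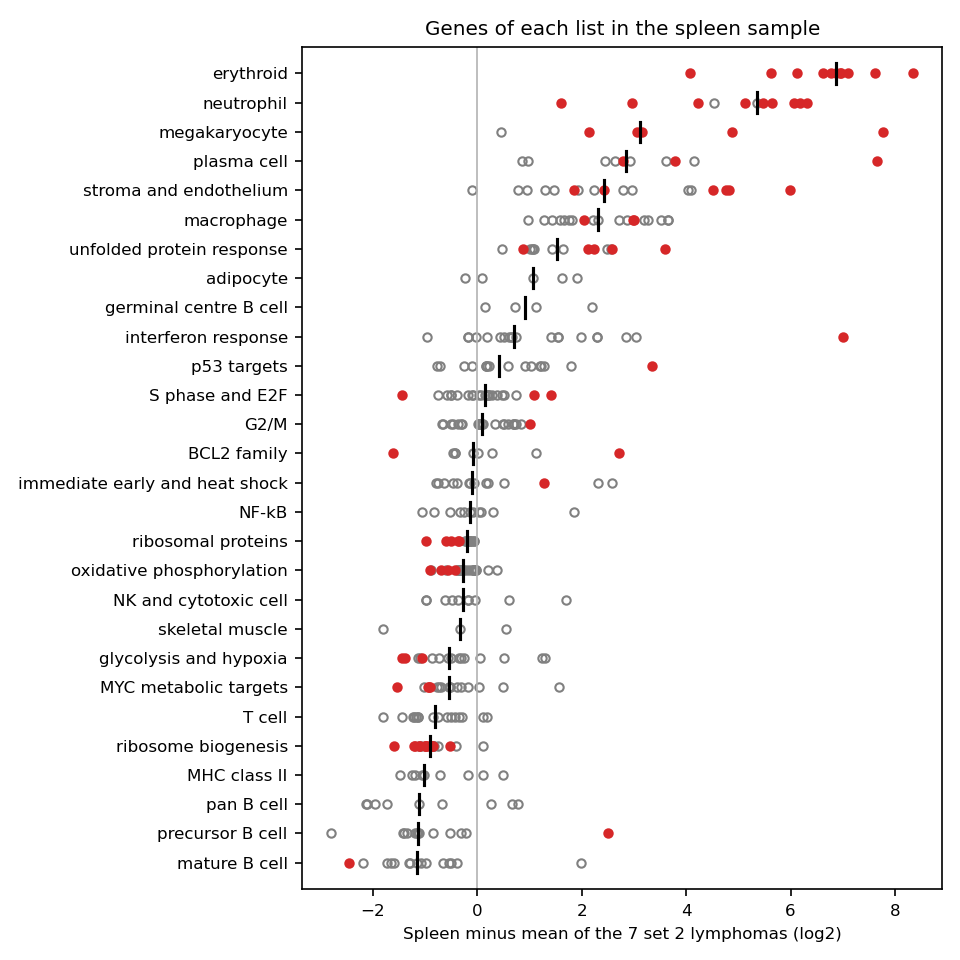
Difference between the spleen and the mean of the 7 lymphomas of set 2 (log2, x axis) for the genes of each list (y axis). Filled points passed the limma threshold, open points did not, and bars are list medians; all 11 erythroid points are filled, and the ribosomal protein points change sign for some genes when the set is left out of the fit.

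The second question was how the lymphomas varied among themselves. After Xist, the transcript of the inactive X chromosome (SD 2.64, n = 43), came Reln (2.59), the precursor B cell transcription factor Sox4 (2.57), the Y-linked Eif2s3y (2.56) and the recombinase gene Rag1 (2.51). Vpreb1, a surrogate light chain gene, had an SD of 2.17 and reached 13.19 in set 1 from a lowest value of 5.24. The secretory genes Igha, Jchain and Ell2 had SDs of 2.51, 2.33 and 2.33, and Cdkn2a had 2.36. The macrophage gene C1qb (2.10), Arg1 (2.28), Cd36 (2.16) and the neutrophil gene S100a9 (2.06) varied similarly, as did Gimap4 (2.12) and Ms4a4b (1.97). Enpep (2.42), Basp1 (2.38), Kcnk1 (2.06), LOC664787 (2.05), Gm6958 (2.04), Slpi (2.03), Cd83 (2.02), the germinal centre gene Gcsam (2.01) and Cnn3 (1.98) completed the 25 most variable genes.

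In all, 608 of 8721 genes (6.97%) had an SD of 1 or more, against a median SD of 0.338, and 23 had an SD of 2 or more. Precursor B cell genes held 10 such genes among 13, macrophage genes 12 among 19, interferon response genes 12 among 20, germinal centre genes 4 among 4, MHC class II genes 6 among 9 and neutrophil genes 7 among 11. Ribosome biogenesis (23 genes), G2/M (23), S phase (23), oxidative phosphorylation (27) and ribosomal protein (16) lists held 0. Without the set correction 654 genes had an SD of 1 or more, and without lymphomas 9, 13, 32 and 40, whose other-cell or B cell scores stood apart, 522 did. Scaled median absolute deviations gave 298.

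Genes of the same list mostly rose and fell together across the 43 lymphomas. Neutrophil genes had the highest mean pairwise correlation, 0.800, led by Ltf and Camp. It was 0.697 for stroma and endothelium (Cav1, Bgn), 0.691 for MHC class II (H2-Eb1, H2-DMa), 0.664 for interferon response (Irf7, Oasl2), 0.664 for adipocyte genes (Adipoq, Car3), 0.611 for G2/M (Ttk, Plk1), 0.600 for macrophage (C1qc, C1qa) and 0.557 for T cell genes (Cd3d, Cd3e). Ribosome biogenesis (Polr1b, Fbl) had 0.528, NF-kB (Cd83, Traf1) 0.527, NK and cytotoxic (Nkg7, Ccl5) 0.506 and S phase (Mcm3, Dut) 0.455. Lower but still past the threshold were pan B cell (0.405), precursor B cell (0.383), unfolded protein response (0.372), MYC metabolic targets (0.363), ribosomal proteins (0.342), plasma cell (0.340), oxidative phosphorylation (0.311), immediate early (0.255), glycolysis and hypoxia (0.216), p53 targets (0.202) and mature B cell (0.194). Thus 23 of 26 lists exceeded random lists of matched expression, most at the smallest permutation p that 10000 draws can give (1e-04, adjusted p = 0.000144). Erythroid (0.179, adjusted p = 0.195), megakaryocyte (0.145, adjusted p = 0.116) and BCL2 family genes (0.041, adjusted p = 0.176) did not. In set 1 alone 23 lists passed, in set 2 alone 19 did, and without the set correction 17 did. Without lymphomas 9, 13, 32 and 40, 24 lists passed, erythroid genes now among them (0.216, adjusted p = 0.0269), and the mean correlation was 0.361 for adipocyte and 0.175 for pan B cell genes. In set 2 the stroma (0.160), ribosomal protein (0.0836), mature B cell (0.0784), immediate early (0.0835) and adipocyte (-0.103) lists did not pass, and megakaryocyte genes did (0.493).

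Lymphomas with high precursor B cell scores had low scores for the antigen presentation genes of MHC class II. Over 43 lymphomas Pearson r was -0.771 (permutation p = 1e-05, the smallest that 100000 permutations can give, adjusted p = 3.83e-05) and Spearman rho was -0.786 (p = 1e-05). Without the 2 lymphomas farthest from the median r was -0.734, in set 1 it was -0.798, and in set 2 it was -0.720 (exact permutation p = 0.0718, n = 7). Precursor and mature B cell scores were inversely related as well (r = -0.567, permutation p = 3e-05, adjusted p = 9.86e-05; rho = -0.605, p = 3e-05). That r was -0.544 without the 2 farthest, -0.584 in set 1 and -0.673 in set 2 (exact permutation p = 0.104, n = 7). Mature B cell and MHC class II scores rose together (r = 0.722, permutation p = 1e-05, adjusted p = 3.83e-05; rho = 0.755, p = 1e-05). Their r was 0.688 without the 2 farthest, 0.740 in set 1 and 0.677 in set 2 (exact permutation p = 0.0927, n = 7).

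**Figure D2:**
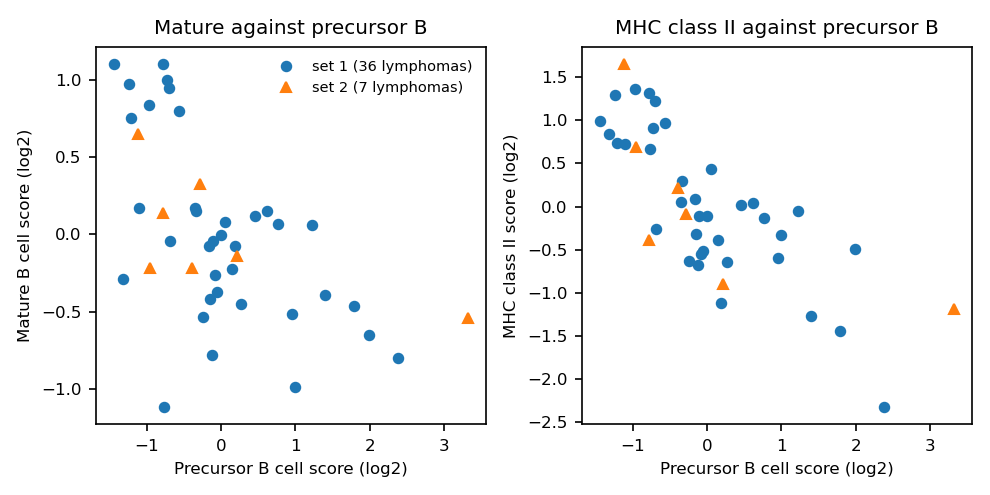
Mature B cell score (left) and MHC class II score (right) against the precursor B cell score in 43 lymphomas, each score the mean of its genes minus the set mean (log2). Circles are set 1 and triangles set 2; r was -0.567 on the left and -0.771 on the right.

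Growth genes followed Myc. The ribosome biogenesis score rose with Myc (r = 0.716, permutation p = 1e-05, adjusted p = 3.83e-05; rho = 0.679, p = 1e-05), with 0.625 without the 2 farthest lymphomas, 0.679 in set 1 and 0.920 in set 2 (exact permutation p = 0.00635, n = 7). The G2/M score rose with Myc less tightly (r = 0.482, permutation p = 0.00145, adjusted p = 0.00303; rho = 0.454, p = 0.00284), with 0.375 without the 2 farthest, 0.446 in set 1 and 0.692 in set 2. With the T cell and macrophage scores held fixed that correlation was 0.107 and no longer passed. Ribosome biogenesis rose with G2/M (r = 0.745, permutation p = 1e-05, adjusted p = 3.83e-05; rho = 0.532, p = 0.00027), with 0.667, 0.780 and 0.524 in the same order. It also rose with oxidative phosphorylation (r = 0.679, permutation p = 1e-05, adjusted p = 3.83e-05; rho = 0.591, p = 6e-05), with 0.656, 0.652 and 0.855. It fell as glycolysis and hypoxia genes rose (r = -0.482, permutation p = 0.00166, adjusted p = 0.00318), but rho was -0.325 (p = 0.0364, adjusted p = 0.0643) and did not pass. That r was -0.538 without the 2 farthest, -0.457 in set 1 and -0.607 in set 2, and it turned to 0.305 without the set correction and to 0.0513 with the T cell and macrophage scores held fixed. The p53 target score was lower where G2/M was higher (r = -0.488, permutation p = 0.0014, adjusted p = 0.00303), with a rho of -0.284 that did not pass (p = 0.0685, adjusted p = 0.105). The corresponding r was -0.420 without the 2 farthest, -0.445 in set 1, -0.804 in set 2, 0.061 without the set correction and -0.0253 with the T cell and macrophage scores held fixed, where it no longer passed.

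Scores of other blood cells moved together in part. The T cell score rose with the interferon response score in the 38 lymphomas that formed the lower group of the latter (r = 0.720, permutation p = 1e-05, adjusted p = 3.83e-05; rho = 0.635, p = 6e-05). Its r was 0.615 without the 2 farthest, 0.757 in set 1 (n = 32) and 0.383 in set 2 (exact permutation p = 0.472, n = 6). T cell and mature B cell scores rose together (r = 0.503, permutation p = 0.00066, adjusted p = 0.0019; rho = 0.398, p = 0.00911), with 0.384 without the 2 farthest, 0.527 in set 1 and 0.352 in set 2. The T cell score fell with G2/M (r = -0.483, permutation p = 0.00127, adjusted p = 0.00303; rho = -0.453, p = 0.00286), with -0.483, -0.484 and -0.479 in the same order, and -0.135 without the set correction, where it no longer passed. T cell and macrophage scores rose together (r = 0.432, permutation p = 0.00435, adjusted p = 0.0077), with a rho of 0.336 that did not pass (p = 0.03, adjusted p = 0.0574), and r was 0.380, 0.382 and 0.672. Stroma and macrophage scores rose together in the 39 lymphomas of the lower stroma group (r = 0.455, permutation p = 0.00497, adjusted p = 0.00816; rho = 0.334, p = 0.0165). Pearson's r rested in part on the 2 farthest lymphomas, since it was 0.284 without them and no longer passed (adjusted p = 0.0825). The rank correlation passed (adjusted p = 0.0345), and r was 0.527 in set 1 (adjusted p = 0.00895), 0.234 in set 2 and 0.495 without lymphomas 9, 13, 32 and 40.

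Of 23 planned pairs 14 passed the threshold, and 14 did without the set correction. In set 2 alone 0 of them passed by exact permutation after adjustment. Cdkn2a did not track the p53 target score (r = 0.00816, permutation p = 0.959) or Myc (r = 0.152, permutation p = 0.337). The precursor B cell and G2/M scores gave r = 0.292 (permutation p = 0.0572), macrophage and interferon response 0.332 (p = 0.0488, adjusted p = 0.0749, with 0.391 in set 1 and -0.486 in set 2), erythroid and macrophage 0.169 (p = 0.277), and plasma cell and unfolded protein response 0.253 (p = 0.109, with 0.412 in set 1 and -0.786 in set 2). The difference between 3' and 5' control probe sets, a sign of RNA quality, gave r = 0.118 with precursor B cell, 0.0439 with ribosome biogenesis and -0.120 with G2/M scores (permutation p = 0.427, 0.784 and 0.452).

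The third comparison asked which genes followed the level of Myc, the oncogene that drives these tumours. Lymphomas with more Myc mRNA expressed more of most ribosome biogenesis genes and less of most germinal centre, plasma cell, T cell and NK cell genes. Per log2 unit of Myc, Fbl rose by 0.36 ± 0.04 (SE, n = 43; limma adjusted p = 6.82e-08), the ribosome assembly gene Wdr12 by 0.57 ± 0.07 (adjusted p = 6.82e-08) and Cad, which starts pyrimidine synthesis, by 0.59 ± 0.07 (adjusted p = 7.49e-08). The germinal centre repressor Bcl6 had a slope of -2.15 ± 0.25 (adjusted p = 4.84e-08) and Jchain, which joins secreted immunoglobulin, one of -2.95 ± 0.42 (adjusted p = 9.6e-07).

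Of 23 ribosome biogenesis genes 20 rose with Myc and 0 fell, or 22 when adjusted over the list alone, including Ddx21 (0.42 ± 0.06, SE) and Nop58 (0.34 ± 0.05). MYC metabolic targets rose in 11 of 17 cases, or 12 when adjusted over the list alone, with the spermidine synthase gene Srm at 0.43 ± 0.07. Of 23 G2/M genes 15 rose, as did 14 of 23 S phase genes, with the same counts when adjusted over each list alone. Nusap1 (0.40 ± 0.07), Aurkb (0.43 ± 0.09) and Ung (0.44 ± 0.07) were examples. Oxidative phosphorylation genes rose in 12 of 27 cases, or 13 when adjusted over the list alone, such as Sdhd (0.31 ± 0.07). Ribosomal protein genes rose in 5 of 16 cases, or 4 when adjusted over the list alone, by small amounts such as 0.09 ± 0.02 for Rpl11. Among all 8720 genes 2301 rose and 1474 fell. No list test was run for any of the regressions, so the list counts here and below have to be read against the counts over all genes. The median slope of all genes was 0.0331, and it was 0.0793 with equal column medians and 0.195 without the set.

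Many T cell, NK cell and macrophage genes fell as Myc rose. T cell genes fell in 14 of 16 cases, with Cd3g at -2.37 ± 0.36 (SE) and Icos at -1.06 ± 0.15. NK and cytotoxic genes fell in 9 of 10 cases (Gzma, -1.62 ± 0.22) and macrophage genes in 11 of 19 (Csf1r, -1.36 ± 0.25), all with the same counts when adjusted over each list alone. Interferon response genes fell in 15 of 20 cases, or 19 when adjusted over the list alone (Cxcl10, -1.34 ± 0.25). Germinal centre genes fell in 4 of 4 cases, including Gcsam (-2.51 ± 0.37), and plasma cell genes in 9 of 10, including Xbp1 (-1.05 ± 0.16), with the same counts when adjusted over each list alone. MHC class II genes fell in 6 of 9 cases, or 8 when adjusted over the list alone (H2-Oa, -1.23 ± 0.24). Of 15 mature B cell genes 6 fell and 1 rose, also when adjusted over the list alone, with Cr2 at -1.89 ± 0.33 and Cxcr5 at -1.64 ± 0.28. The NF-kB list fell in 8 of 11 cases, or 11 when adjusted over the list alone (Icam1, -1.0 ± 0.11), and the unfolded protein response in 10 of 14, also when adjusted over the list alone (Edem1, -1.18 ± 0.16; Hspa5, -0.56 ± 0.10). Of 16 p53 targets 7 fell, or 8 when adjusted over the list alone, with the cell cycle inhibitor gene Cdkn1a at -1.27 ± 0.21.

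Precursor B cell genes rose in 3 of 13 cases, among them Myb (0.96 ± 0.24, SE), and 1 fell, or 3 and 0 when adjusted over the list alone. Glycolysis and hypoxia genes fell in 7 of 16 cases and 1 rose, also when adjusted over the list alone (Ndrg1, -0.81 ± 0.16; Pdk1, 0.40 ± 0.10). Immediate early genes fell in 4 of 14 cases, or 3 when adjusted over the list alone (Dusp1, -1.05 ± 0.20). Neutrophil genes fell in 3 of 11 cases (Csf3r, -0.36 ± 0.07), erythroid genes in 1 of 11 (Car2, -1.56 ± 0.35), both also when adjusted over the list alone, and stroma genes in 1 of 17 (Acta2, -0.58 ± 0.22), or 0 when adjusted over the list alone. BCL2 family genes fell in 2 of 9 cases, or 1 when adjusted over the list alone, skeletal muscle genes rose in 2 of 3, also when adjusted over the list alone, and pan B cell genes rose in 1 of 9, or 0 when adjusted over the list alone. Megakaryocyte (6) and adipocyte (5) genes had 0 past the threshold. The steepest positive slopes belonged to Sox4 (2.29 ± 0.58), 1700097N02Rik (1.89 ± 0.37), Reln (1.89 ± 0.62), Cnn3 (1.83 ± 0.44), Ptgr1 (1.76 ± 0.37), Kcnk1 (1.68 ± 0.48), Thbd (1.67 ± 0.35), Tifa (1.64 ± 0.37), Egfl6 (1.63 ± 0.41) and Uchl1 (1.59 ± 0.46). None of them passed with the T cell and macrophage scores as covariates, and the slope of Reln was 2.22 in set 1 against 0.30 in set 2. After Jchain the steepest negative slopes were those of Basp1 (-2.90 ± 0.45), Gimap4 (-2.62 ± 0.39), Ell2 (-2.54 ± 0.48), Gcsam, Ms4a4b (-2.44 ± 0.36), Cd3g, Cd83 (-2.32 ± 0.40), Smad1 (-2.30 ± 0.28) and Rnf128 (-2.28 ± 0.37). With those covariates Jchain, Gimap4, Gcsam, Smad1 and Rnf128 still passed. Basp1, Ell2, Ms4a4b, Cd83 and Cd3g, a member of the T cell list, did not. Of 126 slopes on Myc of named genes, 83 lost the threshold with them.

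In total 2301 genes rose and 1474 fell with Myc among 8720 tested by limma. With the T cell and macrophage scores as covariates 306 rose and 184 fell, of which 450 were shared, and the list counts became 4 of 23 for ribosome biogenesis, 0 of 23 for G2/M and 0 of 16 for T cell genes, a list that the covariates contain. They became 2 each for germinal centre, plasma cell, NF-kB and unfolded protein response genes, 1 for NK and cytotoxic genes and 0 for MHC class II and interferon response genes. Bcl6 kept a slope of -1.78 (adjusted p = 0.0032) and Fbl one of 0.22 (adjusted p = 0.00896) under these covariates. The germinal centre score split the lymphomas into 36 and 7 (BIC difference 40.5, Ashman D 6.86), and all 7 had Myc below the set mean (-0.44 to -1.31). In the other 36 alone 882 genes rose and 545 fell with Myc, and the counts became 1 of 4 for germinal centre genes (Bcl6), 3 of 10 for plasma cell, 6 of 16 for T cell, 8 of 10 for NK and cytotoxic, 2 of 19 for macrophage and 12 of 20 for interferon response genes. There 12 of 23 ribosome biogenesis and 8 of 23 G2/M genes rose, and 0 of 9 MHC class II genes fell. Without the set 4295 genes rose and 596 fell, in set 1 alone 1921 and 1208, and in set 2 alone 17 and 32.

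**Figure D3:**
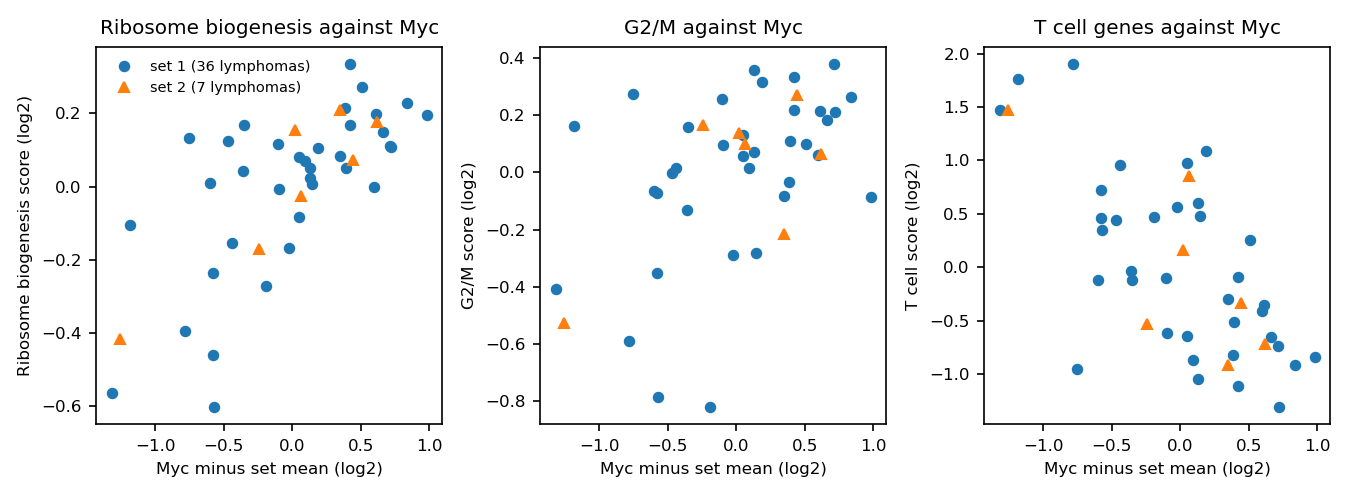
Ribosome biogenesis (left), G2/M (middle) and T cell (right) scores against Myc in 43 lymphomas, all minus the set mean (log2). Circles are set 1 and triangles set 2; r was 0.716 for ribosome biogenesis and 0.482 for G2/M, and the slope of the T cell score was -0.99.

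The fourth comparison used the mature minus the precursor B cell score as a measure of B cell stage. Lymphomas on the mature side had higher MHC class II and germinal centre genes and lower Cd93 and Enpep. Ciita, the master regulator of MHC class II, rose by 0.60 ± 0.06 (SE, n = 43; limma adjusted p = 1.8e-10) per unit of the score and H2-DMb2 by 0.74 ± 0.08 (adjusted p = 9.56e-09). Cd93, a marker of immature B cells, had a slope of -1.08 ± 0.11 (adjusted p = 1.05e-09) and Enpep, the aminopeptidase known as BP-1 on precursor B cells, one of -1.06 ± 0.19 (adjusted p = 8.33e-05).

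Of 9 MHC class II genes 8 rose with the stage score, or 9 when adjusted over the list alone, and 7 did with T cell and macrophage scores as covariates. Germinal centre genes rose in 4 of 4 cases, such as Mef2b (0.69 ± 0.12, SE), also when adjusted over the list alone, and in 1 case with those covariates. The B cell transcription factor gene Spib rose (0.40 ± 0.05) as the only pan B cell gene of 9, also when adjusted over the list alone. NF-kB genes rose in 8 of 11 cases (Birc3, 0.21 ± 0.04; Bcl3, 0.57 ± 0.10), also when adjusted over the list alone, and glycolysis and hypoxia genes in 10 of 16, or 11 when adjusted over the list alone (Pgk1, 0.12 ± 0.02; Slc2a1, 0.26 ± 0.05), while 1 fell. Plasma cell genes rose in 5 of 10 cases, or 7 when adjusted over the list alone (Derl3, 0.47 ± 0.10), and unfolded protein response genes in 7 of 14, or 8 when adjusted over the list alone (Edem1, 0.40 ± 0.07). S phase genes fell in 7 of 23 cases, or 10 when adjusted over the list alone, led by Mcm7 (-0.14 ± 0.02) and Uhrf1 (-0.20 ± 0.04), and in 15 without lymphomas 9, 13, 32 and 40. G2/M genes fell in 1 of 23 cases (Cenpf, -0.14 ± 0.05), or 0 when adjusted over the list alone, and in 13 without those lymphomas. With the T cell and macrophage scores as covariates 6 glycolysis, 2 NF-kB and 1 unfolded protein response genes rose, 1 plasma cell gene fell, 1 S phase gene rose and 3 fell, and 1 G2/M gene rose.

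Macrophage genes rose in 11 of 19 cases on the mature side (Cybb, 0.61 ± 0.13, SE; Apoe, 0.65 ± 0.15), or 13 when adjusted over the list alone, NK and cytotoxic genes in 7 of 10 (Gzmb, 0.74 ± 0.14), or 8 with 1 lower when adjusted over the list alone, and T cell genes in 8 of 16 (Ctla4, 0.35 ± 0.07), also when adjusted over the list alone. With the T cell and macrophage scores as covariates 0 genes of these lists rose, 1 NK gene fell and 1 macrophage gene fell, but the covariates contain the T cell and macrophage lists, so that the loss of their genes is built in. Interferon response genes rose in 4 of 20 cases (Psmb8, 0.20 ± 0.03) and 1 fell, or 5 and 1 when adjusted over the list alone. Without lymphomas 9, 13, 32 and 40, 13 rose, and with those covariates 1 rose and 4 fell. Of 16 p53 targets 6 rose, or 7 with 1 lower when adjusted over the list alone (Zmat3, 0.34 ± 0.11), and 3 of 14 immediate early genes rose, or 5 when adjusted over the list alone (Junb, 0.19 ± 0.04). BCL2 family genes rose in 2 of 9 cases, or 3 when adjusted over the list alone (Mcl1, 0.16 ± 0.03). MYC metabolic targets fell in 4 of 17 cases, also when adjusted over the list alone (Paics, -0.10 ± 0.03), and ribosome biogenesis genes in 3 of 23, or 2 when adjusted over the list alone (Ncl, -0.07 ± 0.02). With the covariates 3 ribosome biogenesis genes and 1 MYC metabolic target rose and 0 fell, and without the 4 lymphomas 7 and 8 fell. Oxidative phosphorylation had 1 gene higher and 1 lower of 27, erythroid 1 lower of 11, stroma 1 lower of 17 (Eng, -0.23 ± 0.05) and adipocyte 1 lower of 5 (Car3, -0.42 ± 0.16), of which only Eng and Car3 passed when adjusted over the list alone, while neutrophil (11), megakaryocyte (6), skeletal muscle (3) and ribosomal protein (16) lists had 0. With the covariates 8 stroma and 3 adipocyte genes were lower.

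The steepest positive slopes on the stage score were those of LOC664787 (1.14 ± 0.12, SE), Ell2 (1.11 ± 0.17), Basp1 (1.04 ± 0.19), the activation marker Cd83 (0.87 ± 0.16), Plek (0.87 ± 0.14), Bcar3 (0.85 ± 0.12), Rnf128 (0.79 ± 0.16), the cathepsin gene Ctsh (0.78 ± 0.08), Rab30 (0.78 ± 0.11) and Slpi (0.77 ± 0.17). After Cd93 and Enpep the steepest negative slopes were Pde2a (-0.88 ± 0.10), Tifa (-0.88 ± 0.12), Alpl (-0.85 ± 0.14), Ptgr1 (-0.82 ± 0.13), Tmem119 (-0.82 ± 0.14), Akap12 (-0.80 ± 0.15), Lgals9 (-0.77 ± 0.10) and Eps8 (-0.77 ± 0.13). In total 999 genes rose and 1133 fell among 8693 tested by limma, and with the T cell and macrophage scores as covariates 477 rose and 688 fell, of which 674 were shared. In the 36 lymphomas of the lower germinal centre group 503 rose and 501 fell, with 7 of 9 MHC class II, 1 of 4 germinal centre, 1 of 16 T cell, 2 of 10 NK and cytotoxic and 1 of 19 macrophage genes higher. Without the set 556 rose and 592 fell, in set 1 alone 870 and 931, and in set 2 alone limma called 0.

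The fifth comparison asked which genes followed Cdkn2a, whose level differed over several log2 units between lymphomas. Few gene groups did. Fhit rose by 0.26 ± 0.06 (SE, n = 43; limma adjusted p = 0.0122) per log2 unit of Cdkn2a, Slc12a2 by 0.24 ± 0.06 (adjusted p = 0.0248) and Ift74 by 0.20 ± 0.04 (adjusted p = 0.00242). Ramp1 had a slope of -0.31 ± 0.09 (adjusted p = 0.0403) and the kinase gene Csnk1e one of -0.25 ± 0.05 (adjusted p = 0.00334).

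Of 16 p53 targets 0 followed Cdkn2a, or 1 fell when adjusted over the list alone. Oxidative phosphorylation genes rose in 2 of 27 cases (Ndufa4, 0.06 ± 0.01, SE; Uqcrq, 0.06 ± 0.01) and fell in 1 (Sdha, -0.07 ± 0.02), or 11 and 3 when adjusted over the list alone. Ribosome biogenesis genes rose in 2 of 23 cases (Nip7, 0.06 ± 0.01), MYC metabolic targets in 2 of 17 (Eif4e, 0.07 ± 0.02) and G2/M genes in 1 of 23 (Mad2l1, 0.06 ± 0.02), with the same counts when adjusted over each list alone. The replication gene Fen1 fell (-0.09 ± 0.02) as the only S phase gene of 23, or 2 when adjusted over the list alone, and the glycolysis gene Pkm rose (0.07 ± 0.02) as the only member of 16, or 4 with 1 lower when adjusted over the list alone. Neutrophil genes fell in 1 of 11 cases, Mpo (-0.24 ± 0.07), or 7 when adjusted over the list alone, and the kinase gene Syk fell (-0.12 ± 0.03) as the only pan B cell gene of 9, also when adjusted over the list alone. The muscle gene Mylpf rose (0.15 ± 0.03) as 1 of 3, or 2 when adjusted over the list alone, and Rplp0 rose (0.02) as 1 of 16 ribosomal protein genes, or 1 with 1 lower when adjusted over the list alone. The other lists had 0 genes past the threshold among all genes, and adjusted over the list alone 1 megakaryocyte gene rose and 2 BCL2 family genes fell.

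The other steepest slopes on Cdkn2a were positive for Slc25a13 (0.26 ± 0.08, SE), Slc30a4 (0.23 ± 0.05), Pfn2 (0.21 ± 0.06), Gas2 (0.20 ± 0.05), Map7 (0.19 ± 0.06), Paip2b (0.19 ± 0.05) and Trim32 (0.18 ± 0.05). They were negative for Aldh1b1 (-0.29 ± 0.06), Actn1 (-0.28 ± 0.07), Fxyd5 (-0.26 ± 0.07), Kmo (-0.25 ± 0.06), Pard6g (-0.25 ± 0.06), Mpo, Spint2 (-0.24 ± 0.06) and Prodh (-0.22 ± 0.06). Without lymphomas 9, 13, 32 and 40, Ramp1, Slc25a13, Pfn2, Map7, Fxyd5 and Mpo no longer passed. With the T cell and macrophage scores as covariates Ramp1, Pfn2, Trim32, Fxyd5, Kmo, Mpo and Spint2 did not pass. In total limma called 288 genes positive and 129 negative among 8720. These counts were unsteady, with 41 and 3 without the set, 95 and 29 with the RNA quality measure as a covariate, 110 and 43 without the 2 lymphomas farthest from the median, and 136 and 41 in set 1 alone against 1 and 1 in set 2 alone. Array weights raised them to 769 and 504, and the 36 lymphomas of the lower germinal centre group gave 399 and 179.

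Xist and the Y-linked genes split most lymphomas into 2 groups. In set 1, 15 lymphomas had Eif2s3y between 7.67 and 9.38 with Xist between 6.29 and 7.44, and 20 had Eif2s3y between 3.03 and 4.01 with Xist between 10.79 and 12.78. In set 2 the corresponding numbers were 2 and 4. Kdm5d and Uty followed Eif2s3y, with Kdm5d between 5.89 and 7.0 in the first group of set 1 and between 3.69 and 4.30 in the second, and Uty between 4.42 and 6.9 and between 3.20 and 3.92. Lymphoma 33 combined an Xist level of 9.25 with an Eif2s3y level of 8.49, and lymphoma 37 combined 6.75 with 4.62. The spleen had Xist at 6.71 and Eif2s3y at 8.15.

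**Figure D4:**
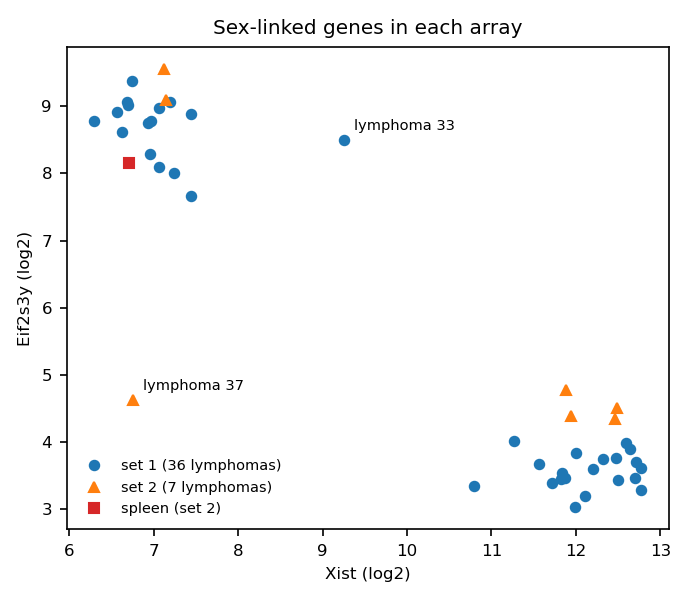
Eif2s3y against Xist (log2) in the 43 lymphomas and the spleen. Circles are set 1, triangles set 2 and the square the spleen; lymphoma 33 (9.25, 8.49) and lymphoma 37 (6.75, 4.62) lie outside the 2 groups.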

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

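The results were recomputed under alternatives that changed 1 choice at a time, except that leaving out the set also changed the filter, from 8721 genes to 9103. This gave 9716 values, of which 8499 were counted as unchanged, 945 lost the threshold and 182 gained it. Another 40, all counts or SDs, moved beyond a set margin, and 50 turned direction with the main or the alternative value past the threshold. A turn of direction with neither value past the threshold was counted as unchanged, so 50 is not the number of all turns. The causes of these changes were not tested, except where the alternative's own construction gives them. The set covariate was chosen after seeing the data, which made the fit without the set, planned first, an alternative. The fits within a set, without lymphomas 9, 13, 32 and 40, with 6 other-cell scores and with the spread of the set 2 lymphomas alone were also chosen after seeing the data, as were array weights and the 3' minus 5' covariate for the lists in the spleen, and the 36 lymphomas of the lower germinal centre group. No background level was measured, and the median levels of stroma, adipocyte, megakaryocyte and erythroid genes in set 1 (5.69, 5.44, 5.45 and 4.86) lay under the median of all probe sets (6.28). No paired analysis was possible because no labels pair the samples, and not every alternative was run for every result.

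The count of 1168 genes in the spleen was 743 with a filter on the mean, 1772 over single probe sets (more features tested), 2449 with array weights and 1806 when counted as outside the lymphoma range, against 819 to 1437 elsewhere. Its 11 lists became 7 with the filter on the mean and 2 with an estimated correlation, against 9 to 13 elsewhere. Igk turned to 0.82 when its probe sets were averaged. Without the set Sdhb (0.10), Uqcrc2 (0.23), Cox5a (0.12), Rpl11 (0.12), Rpl27 (0.28) and Rps19 (0.29) turned positive, since all set 2 columns lie higher, and the ribosomal protein list gave adjusted p = 0.933 upward.

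The 608 genes with an SD of 1 or more became 376 with the filter on the mean, 298 by median absolute deviation and 23 at an SD of 2. Adipocyte coherence was -0.103 in set 2 alone.

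With T cell and macrophage scores partialled out, computed only for pairs that hold neither score, 6 of the 9 such pairs that had passed did so, and Myc and G2/M gave 0.107, p53 targets and G2/M -0.0253, and ribosome biogenesis and glycolysis 0.0513. By Spearman, ribosome biogenesis and glycolysis (-0.325), p53 targets and G2/M (-0.284) and T cell and macrophage (0.336) did not pass. Without the set, ribosome biogenesis and glycolysis gave 0.305, p53 targets and G2/M 0.0609 and T cell and G2/M -0.135, while precursor B cell and G2/M (0.357), macrophage and interferon response (0.370) and plasma cell and unfolded protein response (0.402) passed. Macrophage and interferon response also passed with the filter on the mean (0.391), the title number partialled out (0.380), set 1 alone (0.391) and without the 2 farthest lymphomas (0.413), whereas set 2 gave -0.486 (exact permutation p = 0.321, n = 6). Stroma and macrophage fell to 0.284 without the 2 farthest. Plasma cell and unfolded protein response passed in set 1 (0.412), whereas set 2 gave -0.786 (exact permutation p = 0.0458, n = 6). Precursor B cell and G2/M passed without lymphomas 9, 13, 32 and 40 (0.417). In set 2, with 7 or 6 lymphomas, 0 passed by exact permutation after adjustment. The values there were -0.673 for precursor and mature B cell, -0.720 for precursor B cell and MHC class II, 0.677 for mature B cell and MHC class II, 0.920 for Myc and ribosome biogenesis, 0.692 for Myc and G2/M, 0.524 for ribosome biogenesis and G2/M, 0.855 for ribosome biogenesis and oxidative phosphorylation and -0.607 for ribosome biogenesis and glycolysis. They were -0.804 for p53 targets and G2/M, 0.672 for T cell and macrophage, -0.479 for T cell and G2/M, 0.383 for T cell and interferon response, 0.234 for stroma and macrophage, and 0.352 for T cell and mature B cell.

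The 3775 genes on Myc became 490 with T cell and macrophage scores as covariates, 321 with 6 other-cell scores, 5955 over single probe sets (more features tested) 1427 in the 36 lymphomas of the lower germinal centre group and 49 in set 2 alone (fewer samples). Slopes on Myc that turned with the T cell and macrophage scores were Vpreb3 (-0.0597), Ciita (0.0029) and Mylpf (-0.0146). With the 6 scores, which contain some of these genes, they were Tifa (-0.0435), Ms4a4b (0.108), Cd83 (0.0318), Myb (-0.0914), Vpreb3 (-0.0773), H2-DMa (0.0109), H2-Ab1 (0.0354), Ciita (0.0265), Cd3d (0.0827), Nkg7 (0.368), Mylpf (-0.0368), Iigp1 (0.203) and Igtp (0.418). In the 36 lymphomas Ciita (0.0493), Tnni2 (-0.0145) and Mdm2 (0.0211) turned, and in set 2 Mmp8 (0.0526).

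The 2132 genes on the stage score became 1165 with T cell and macrophage scores, 743 with 6 scores, 1148 without the set, 1004 in the 36 lymphomas and 0 in set 2. Slopes turned for Prdm1 (-0.0171), Cad (0.0049), Iigp1 (-0.0679) and Gbp2 (-0.0559) with the first, and with the 6 scores for Bcl6 (-0.0547), Creld2 (-0.0334), Prdm1 (-0.105), Icos (-0.0453), Gnl3 (0.0348), Nop56 (0.0245), Cad (0.0203), Igtp (-0.0387), Iigp1 (-0.0313), Gbp2 (-0.205), Sel1l (-0.0032) and Hspa5 (-0.0041). In the 36 lymphomas Bcl6 turned to -0.0974.

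The 417 genes on Cdkn2a became 124 with the 3' minus 5' covariate, 152 with 6 scores, 1273 with array weights, 779 over single probe sets, 276 with ranks, 177 in set 1, 2 in set 2, 153 without the 2 farthest lymphomas and 44 without the set. Pard6g turned to 0.0082 in set 2.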

Other observations

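A distinct group of lymphomas expressed germinal centre genes. Lymphomas 4, 8, 21, 22, 30, 36 and 39 had germinal centre scores of 1.73 to 3.41, whereas the other 36 lay between -1.43 and 0.50. In this group Bcl6, the repressor needed for germinal centres, stood 1.63 to 3.80 above its set mean, and Gcsam, a germinal centre signalling adaptor, 1.47 to 5.28. Both belong to the list by which the group was found, so their values are no separate evidence. In set 1 Bcl6 ranged from 4.68 to 10.34, Mef2b from 4.67 to 9.39 and Lmo2 from 6.61 to 11.11. In all 7, Myc lay below its set mean (-0.44 to -1.31). In the order of the numbers above, their T cell scores were 1.90, 0.96, -0.95, 0.46, 1.47, 1.76 and 1.47 and their NK and cytotoxic scores 2.42, 1.0, 0.17, 0.67, 1.68, 2.47 and 1.90, so that the group was not uniform in these. Of the 7 lymphomas 6 were also among the 10 with high NF-kB scores. The NK, stroma, interferon, megakaryocyte and unfolded protein response scores also split into separate groups, with 9, 4, 5, 6 and 3 lymphomas in the higher one. The megakaryocyte list had not passed the coherence test, and the mean scores of its groups were -0.06 and 0.36. Its median level in set 1 (5.45) lay under the median of all probe sets (6.28).

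A few lymphomas stood apart by their scores for cell type lists. Lymphoma 13 had an adipocyte score of 6.05, a stroma score of 4.15, a macrophage score of 2.77 and an interferon score of 3.52, against at most 2.70, 2.05, 2.54 and 2.0 in 39 others. With the spread of all other arrays, the spleen included, it was set against the other lymphomas of set 1 by limma. Since it was chosen by these scores, genes of their lists are no separate evidence, and neither are other genes that vary with them. Genes outside the lists among the highest were Mgp (6.97 ± 1.09, SE), Rgs5 (6.96 ± 1.20) and Lum (6.54 ± 0.43). Whether these vary with the listed genes was not tested. Lymphomas 9, 32 and 40 had pan B cell scores of -1.96, -3.00 and -1.18, against -0.29 to 0.65 in 39 others, and that of lymphoma 13 was -0.83. The T cell, macrophage, stroma and adipocyte scores of lymphomas 9, 32 and 40 lay within the ranges of the 39 others. In lymphoma 32, fitted in the same way, higher genes included Cdh1 (6.26 ± 0.89), the cytokine gene Il18 (6.23 ± 1.02), the desmosome gene Dsp (5.62 ± 0.81) and Cd7 (5.12 ± 1.13). Lower genes outside the pan B cell list, by which it was chosen, included Cd22 (-4.14 ± 0.66) and Cd81 (-4.19 ± 0.54). Cd22 is a member of the mature B cell list, and the mature B cell score of lymphoma 32 (-1.12) was the lowest among the lymphomas. Genes that vary with the pan B cell list are no separate evidence either. The 3' minus 5' control difference of lymphoma 32 was 0.93, against 0.41 ± 0.27 (SD, n = 36) in set 1. Its G2/M score of -0.82 was the lowest among the lymphomas.

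The tests of the first and second of the patterns below were chosen after the result was seen. Of 45 T cell, NK cell and macrophage genes 34 (75.6%) fell past the threshold as Myc rose. Whether different numbers of these cells among the lymphomas account for this cannot be told apart, because that share only restates the pattern. RNA quality as the whole cause was argued against, since all 34 stayed past the threshold with the 3' minus 5' control difference as a covariate. Whether a general share of non-lymphoma cells could account for the pattern cannot be told apart, because the T cell slope lay 0.92 below that of stroma (a difference of -0.92 ± 0.31, SE, and -1.11 ± 0.26 without lymphoma 13), but 13 of the 17 stroma genes had a set 1 mean under the median of all probe sets. No sort that would remove such cells is stated by the labels. Apart from the numbers of these cells, no biological explanation was tested, and the labels give no groups among the lymphomas. The 7 lymphomas with high germinal centre scores all had Myc below the set mean, and the pattern was weaker without them. In the other 36, 6 of 16 T cell, 8 of 10 NK and cytotoxic and 2 of 19 macrophage genes fell past the threshold. The median slopes there were -0.74, -1.12 and -0.49, against -0.97, -1.52 and -1.17 in all lymphomas.

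Lymphomas 33 and 37 did not show 1 sex by Xist and the Y-linked genes. In lymphoma 33 Xist at 9.25 lay between the 2 groups of set 1, above 7.44 and under 10.79, while Eif2s3y at 8.49 was high, so that cells of a male and a female mouse in 1 sample may be a candidate explanation. In lymphoma 37 Xist at 6.75 lay below the 7.12 to 7.14 of the Y-high lymphomas of set 2 while Eif2s3y at 4.62 lay within the range of the Y-low ones, which argues against such a mixture. A change of the sex chromosomes in the tumour was not tested and stays open for both, and no biological explanation was tested.

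Ift74, a chromosomal neighbour of Cdkn2a with 3 measured genes between them on chromosome 4, rose with Cdkn2a. Copy number of the segment may contribute, since the median slope of the 19 other measured neighbours, 0.0432, lay at percentile 99.0 of 8348 windows of neighbouring genes (median 0.00171, 95th percentile 0.0300). Of the 19, 14 had a positive slope and only Plaa (0.07 ± 0.02, SE, adjusted p = 0.0122 by limma) passed the threshold. Plaa lies next to Ift74. The genes that flank Cdkn2a, Mtap (0.06 ± 0.05, SE) and Cdkn2b (0.04 ± 0.02), did not pass, and neither did Caap1 beyond Cdkn2b (-0.0015 ± 0.022). The window median therefore does not place a change of copy number at Cdkn2a itself. Shared regulation of neighbouring genes was not tested and stays open, and so does every biological explanation.

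Other arrangements of the samples gave fewer genes in each comparison. Of the 44 arrays singled out in turn only 1, the spleen, gave as many as its 1168 genes, and the highest other was 990, from lymphoma 13. With 1 spleen, 1 of 44 is the smallest share possible, and it does not separate the tissue from an unusual sample. Of 100 orders of the Myc values within the sets only 1, the real one, gave as many as 3775, and the highest other was 270. The same held for the stage score (1 of 100, with 2132 against 1) and for Cdkn2a (1 of 100, with 417 against 36). With 100 orders 1 of 100 is the smallest share possible, so chance is not excluded beyond that. The 3 predictors are expression values of the same arrays, and shuffling breaks co-expression of any source, so the orders do not tell sources apart.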
